A study of Homo sapiens with 6 samples.

How the data were processed

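Total RNA of NB4 cells, control or treated with arsenic trioxide for 6 h, was depleted of ribosomal RNA and made into libraries, per the labels' protocols, with a kit that does not mark strand. There were 3 libraries per group. The submitters' processing notes name HISAT2 2.1.0, HTSeq, DESeq2 and the genome build hg38, without parameters. Duplicate reads were removed by the authors, per the file headers, which carry that mark in each library's column name. The deposited table holds RPKM of 23858 genes in the 6 libraries, and the values fit reads divided by exon length and by the library's reads counted in genes, with no further factor between libraries. The same table holds the authors' comparison of the groups. Per the file headers it gives a mean normalized signal over the 6 libraries, a log2 fold change with its standard error, a test score (the fold change over its error), a p-value and an adjusted p-value. The direction of the deposited log2 fold change, arsenic trioxide over control, was read from the values. The fold changes, scores and p-values of the authors were not used in any test here and are quoted only as the authors' values, while the mean served to settle exon lengths for the recovered reads.

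Each deposited RPKM value was turned back into whole reads with the exon length of the gene in GENCODE release 29 (GRCh38, the build called hg38) and 1 total per library. All 6 values of a gene came out whole, within a tolerance of 0.01 reads, for 93.0% of genes from that length alone and for 100.0% once the deposited mean was used to settle the length. Library totals were 19361333 to 22609019 reads. Whether a read stands for a read or a pair is not given in the sources used here. The lowest sum over the 6 libraries was 21 reads, so only genes with more than 20 reads are listed, and genes below that were not analysed here. The annotation lacks 151 of the listed genes, and 358 symbols occur more than once. Coordinates are those of GENCODE 29, counted from 1.

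Because the file holds RPKM and not counts, the test fixed for normalized values was used in place of the count test planned first. Log2 of RPKM + 1 was tested with limma 3.58.1 (R 4.3.3) in its trend mode, with treatment as the only term and all 6 libraries. Genes with a mean of at least 1 RPKM over the 6 libraries were kept, which left 16803 and set aside 7055. P-values were adjusted with the Benjamini-Hochberg method and called under 0.05. Calls with a log2 fold change of at least 1 in size were counted as at least 2-fold. The 31 gene lists cover metallothionein and zinc, heat shock, NRF2, the integrated stress response, endoplasmic reticulum chaperones, p53, immediate early genes, NF-kB, interferon, retinoic acid, granulocyte maturation, promyelocyte granules, myeloid regulators, the BCL2 family, G1/S, G2/M, histones, the proteasome, autophagy, PML bodies and SUMO, arsenic handling, coagulation, hypoxia, cholesterol, ribosomal proteins, mitochondrial DNA, ribosome biogenesis and 4 groups of other cell types. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, with the Benjamini-Hochberg method over the 28 lists, and beside it with an estimated correlation and with limma's fry.

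The genes named were set by rule. A set of 15 genes is reported whatever the result. The 10 largest rises and 10 largest falls were taken among called genes whose groups did not overlap and whose symbol is not clone-based, with the filter of 1 RPKM standing in for one on CPM. For each list described, up to 4 members with the smallest p-values are named. Library totals and shares were compared between groups with an exact two-sided permutation test over the 20 assignments, whose smallest p is 0.1. A chi-square per degree of freedom of reads between libraries of a group was 5.48 to 13.5, far above 1, so no library is a copy of another.

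The test was checked on simulated reads drawn for the real genes and libraries, with 16776 genes tested in a simulated comparison of arsenic trioxide and control. Limma-trend recovered 27.3% of 66 genes changed 1.5-fold, 80.6% of 62 changed 2-fold and 96.9% of 64 changed 4-fold, with 11 false calls among 141. Limma-voom recovered 65.2%, 88.7% and 96.9%, with 9 false calls among 169. The set test called the 1 simulated list that was shifted and 0 of the others. All simulated genes were drawn independently of one another, with 1 shared spread. This check therefore cannot tell how the set test behaves where genes vary together. In the real libraries the correlation estimated for the shifted list, ribosome biogenesis, was 0.287. Few genes were changed in the simulated comparison, so its shares of recovered genes do not carry over to the real data.

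The alternatives tried were median-ratio and upper quartile factors applied to RPKM, no filter, a filter at 1 CPM on the recovered reads, limma-voom on the recovered reads, pseudocounts of 0.1 and 5, the replicate number as a block, leaving out mitochondrial, ribosomal and small structural RNA genes, and leaving out each library in turn. Leaving out genes that overlap another listed gene was added after the data were seen.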

Results

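RNA of NB4 cells was sequenced after 6 h with arsenic trioxide and without it. NB4 is a human acute promyelocytic leukaemia line that carries the PML-RARA fusion gene, and arsenic trioxide is a drug used against this leukaemia that leads to degradation of the fusion protein. There were 2 groups, control and arsenic trioxide, with 3 libraries each. The dose is not given in the sources used here. Expression was deposited as RPKM, reads scaled to exon length and to the library's counted reads, for 23858 genes, of which 13480 are protein-coding in the annotation. Whole reads recovered from these values came to 20201121, 19361333 and 22609019 in control replicates 1, 2 and 3. The arsenic trioxide replicates held 22300255, 21185966 and 21976255 reads. An exact two-sided permutation test of these totals gave p = 0.4 (n = 3 each), with 0.1 the smallest p that 3 against 3 allows. At this depth 3 reads in a gene with 1 kb of exon correspond to 0.133 to 0.155 RPKM, a floor that covers counting error only. Correlations and principal components used log2 of RPKM + 1 of the 16803 genes with a mean of at least 1 RPKM. Pearson's r across these genes, which are not independent replicates, was 0.965 to 0.973 within groups and 0.919 to 0.935 between them. The first principal component, with 55.3% of the variance, separated the groups. The second, with 15.2%, set control replicate 1 (21.3) and arsenic trioxide replicate 3 (23.0) apart from the other 4 libraries (-14.9 to -6.85). Whether the replicates were separate cultures is not given in the sources used here, so the p-values measure only the spread between these samples.

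The comparison asks which genes change expression within 6 h of arsenic trioxide, which the series title ties to degradation of the fusion protein. No protein was measured here. Most tested members of the NRF2 antioxidant (20 of 23), cytosolic heat shock (19 of 23) and integrated stress response (23 of 24) lists rose, and 12 of 20 regulators of the myeloid lineage fell. HMOX1, which encodes the haem-degrading enzyme heme oxygenase 1 (chromosome 22, 35380361 to 35394214, GRCh38), went from 0.954 ± 0.287 to 275 ± 64.5 RPKM (SD, n = 3 each), a 288-fold rise. MT2A, a metal-binding metallothionein (chromosome 16, 56608199 to 56609497), rose from 46.0 ± 3.29 to 309.8 ± 11.8 RPKM. MYC, a transcription factor that drives growth (chromosome 8, 127735434 to 127741434), fell from 177 ± 11.7 to 55.0 ± 8.60 RPKM, and GFI1, a transcriptional repressor needed for granulocyte development (chromosome 1, 92474762 to 92486876), fell from 61.3 ± 1.46 to 19.1 ± 2.57 RPKM.

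Of 16803 genes tested with limma-trend, 2021 were higher and 2252 lower after arsenic trioxide (Benjamini-Hochberg adjusted p under 0.05), together 25.4%. The fitted change was at least 2-fold in 343 of the higher and 260 of the lower genes. These counts depend on the pseudocount of 1, and were 564 and 464 with 0.1 and 87 and 58 with 5. The median log2 fold change of all tested genes was -0.0033, the median size among the called genes was 0.56, and the median standard error was 0.13. Protein-coding genes made up 10159 of the tested genes, of which 1456 rose and 1696 fell. Among the 6644 other genes, 565 rose and 556 fell. The 3 treated and 3 control libraries did not overlap in 7489 of the tested genes, 44.6%, where chance gives 10%. The span of 61.7% of the called genes and 67.9% of the tested genes overlaps another listed gene, and since the libraries do not mark strand, reads from a stretch shared by 2 genes cannot be told apart. Without arsenic trioxide replicate 1 or control replicate 3 the count of higher genes was 1331 or 1341, and without control replicate 2 or 3 the count of lower genes was 1427 or 1487. The authors' deposited table gave an adjusted p under 0.05 to 4922 of the tested genes, of which 3820 were also called here, each with the same sign.

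**Figure D1:**
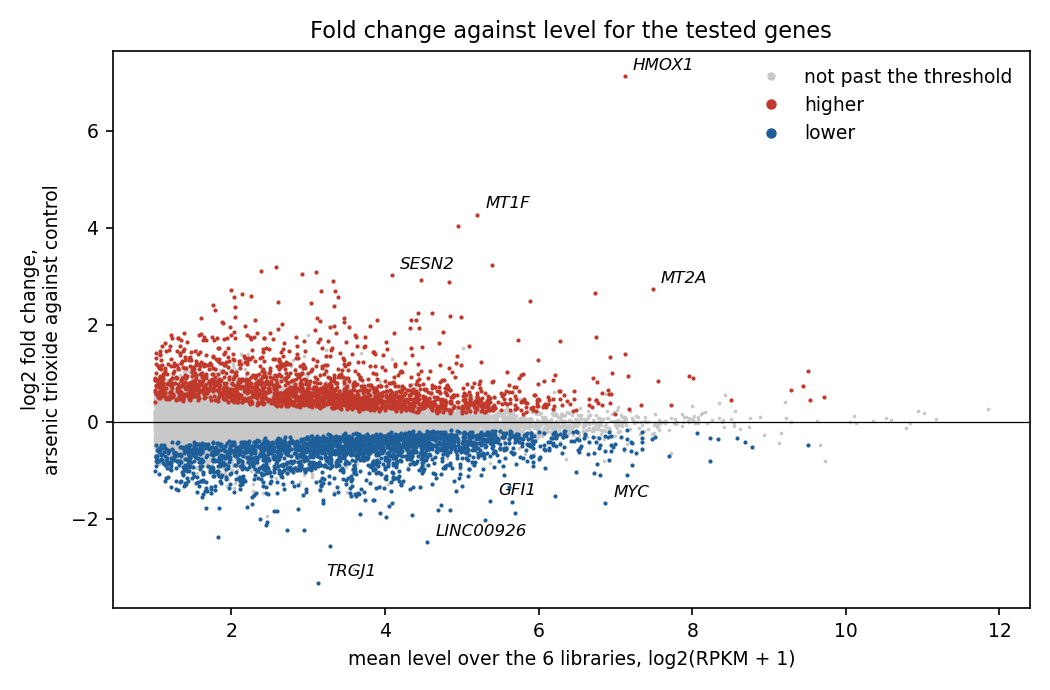
Log2 fold change of each tested gene (arsenic trioxide minus control, log2 of RPKM + 1) against its mean level over the 6 libraries (log2 of RPKM + 1), with the 2021 higher and 2252 lower genes coloured. HMOX1 lies highest at 7.13, and most of the 343 genes with at least a 2-fold rise lie above a dense band around 0.

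Ranked by the fitted change of log2 of RPKM + 1, which shrinks folds of genes at low RPKM, the 10 largest rises among genes whose groups did not overlap were led by HMOX1 (log2 fold change 7.13 ± 0.19 SE, limma-trend adjusted p = 2.13e-05), followed by the metallothioneins MT1F (4.27, from 2.75 ± 1.37 to 68.7 ± 6.59 RPKM) and MT1X (4.04, from 2.57 ± 0.865 to 57.1 ± 8.85 RPKM). The metallothionein genes resemble one another in sequence, so how reads were divided among MT1F, MT1X and MT2A is uncertain. HTRA3, a secreted serine protease, rose from 7.51 ± 4.62 to 74.6 ± 23.3 RPKM (log2 fold change 3.24). The non-coding RNA LUCAT1 rose from 0.176 ± 0.0662 to 9.75 ± 1.53 RPKM (3.18), a 55.4-fold ratio of group means where that of MT1F was 25.0-fold. SESN2, a stress-induced inhibitor of growth signalling, rose from 2.47 ± 0.224 to 29.5 ± 14.3 RPKM (3.02). FAM129A rose from 4.18 ± 0.356 to 38.2 ± 3.09 RPKM (2.92). AKR1C7P, a pseudogene that can share reads with its AKR1C relatives, had a log2 fold change of 2.91. SLC7A11, the cystine importer that feeds glutathione synthesis, rose from 5.76 ± 0.976 to 49.0 ± 9.53 RPKM (2.88), and MT2A had a log2 fold change of 2.73 ± 0.07 SE (limma-trend adjusted p = 2.13e-05).

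Among the 10 largest falls, TRGJ1, a joining segment of the T cell receptor gamma locus (chromosome 7, 38269491 to 38269540), had a fitted log2 fold change of -3.31 that rests on a mean of 15.3 reads per control library and 0.667 reads per treated library. The olfactory receptor pseudogene OR8R1P fell from 15.7 ± 1.74 to 1.84 ± 0.213 RPKM (-2.56), and the long non-coding RNAs LINC00926 and LINC01264 had log2 fold changes of -2.47 and -2.23. DHRS9, a retinol dehydrogenase, fell from 9.87 ± 1.31 to 1.32 ± 0.20 RPKM (-2.23), and GPR141, an orphan receptor, from 7.89 ± 1.39 to 1.04 ± 0.439 RPKM (-2.14). The small nucleolar RNAs SNORD105 (-2.06) and SNORD105B (-2.01) lie within PPAN, which itself, named after its values were seen, had a log2 fold change of -0.79, and each had a mean of 2.0 reads in the treated libraries. ZFP36L2, which promotes decay of AU-rich messenger RNAs, fell from 31.3 ± 4.13 to 7.55 ± 1.5 RPKM (-1.93). MYB-AS1 (-1.91) overlaps MYB on the other strand, so its reads cannot be told apart from those of MYB.

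**Figure D2:**
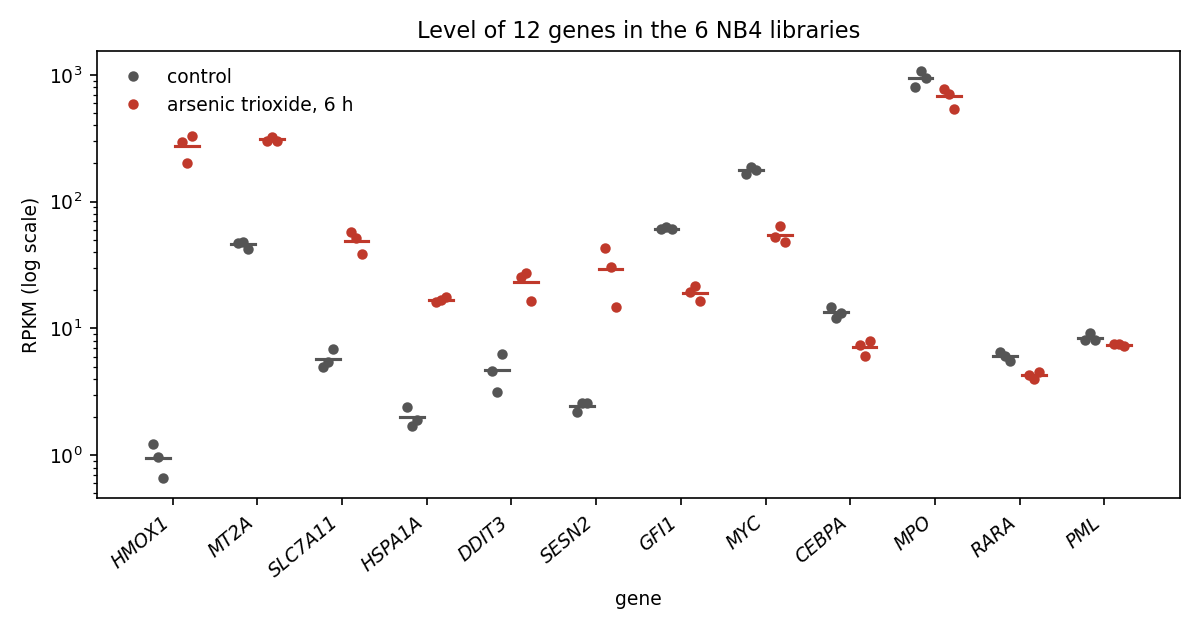
RPKM in each of the 6 libraries (log axis), control and arsenic trioxide side by side, for 12 of the genes named, with the group mean as a bar. HMOX1, MT2A, SLC7A11, HSPA1A, DDIT3 and SESN2 lie higher in each treated library than in any control library. GFI1, MYC, CEBPA, RARA, MPO and PML lie lower, though the changes of MPO and PML were not called.

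Of the genes of the fusion, RARA (chromosome 17, 40309192 to 40357643) fell from 6.06 ± 0.514 to 4.27 ± 0.262 RPKM (log2 fold change -0.42, limma-trend adjusted p = 0.0256). This call was lost without control replicate 1 (adjusted p = 0.0753) or 2 (0.0727) and without arsenic trioxide replicate 1 (0.068) or 2 (0.0749). It was also lost with the replicate number as a block (0.0682). PML (chromosome 15, 73994673 to 74047812) was at 8.45 ± 0.683 and 7.44 ± 0.126 RPKM (-0.16, adjusted p = 0.21). Reads of the fusion transcript fall within both genes, and the fusion was not quantified. CEBPA, a regulator of granulocyte fate, fell from 13.4 ± 1.37 to 7.16 ± 1.03 RPKM (-0.83, adjusted p = 0.00433). SPI1, which encodes the myeloid factor PU.1, was at 27.2 ± 3.28 and 26.2 ± 0.652 RPKM (-0.04, adjusted p = 0.743). CEBPE, a factor of late granulocyte maturation, was at 23.3 ± 6.20 and 16.4 ± 3.34 RPKM (-0.46, adjusted p = 0.132). MPO, the myeloperoxidase of primary granules, was at 940.0 ± 132 and 677 ± 123 RPKM (-0.48, adjusted p = 0.0716). For CEBPE and MPO the authors' deposited table lists an adjusted p of 0.0186 and 0.00252. ITGAM, the CD11b surface marker of maturing granulocytes, was at 3.99 ± 0.447 and 4.85 ± 0.797 RPKM (0.23, adjusted p = 0.268). CDKN1A, the p21 cell cycle inhibitor, was below the filter at 0.17 ± 0.119 and 0.714 ± 0.378 RPKM and was not tested here. The authors' deposited table lists a log2 fold change of 2.04 for CDKN1A, with an adjusted p of 0.000991.

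Before the data were examined, 31 gene lists, the genes reported whatever their result, the tests and all but 1 of the other settings were fixed. Of the 28 lists with at least 5 tested members, 15 passed limma's camera test with its preset correlation of 0.01 (Benjamini-Hochberg adjusted p under 0.05), 9 upward and 6 downward, and 0 held with a correlation estimated from these libraries, where 7 lists had an unadjusted p under 0.05. That estimate rests on 4 residual degrees of freedom, as does the test that uses it. Calls were also lost where the estimate lay below 0.01, as for the metallothionein and zinc (-0.023), myeloid regulator (-0.021) and p53 (-0.051) lists. The loss of the calls is therefore not due to correlation between genes alone. The fry test, which asks whether a list's genes move on balance one way without comparing them with other genes, also called 15 lists, though not the same ones. It did not call the endoplasmic reticulum chaperone (adjusted p = 0.0887), interferon (0.0509) and G1/S (0.0504) lists, and it called the BCL2 family (0.000661), PML body and SUMO (0.0131) and arsenic handling (0.0197) lists, which camera did not. Where no other count is given for a list adjusted over the list alone, it equals the count over all genes.

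**Figure D3:**
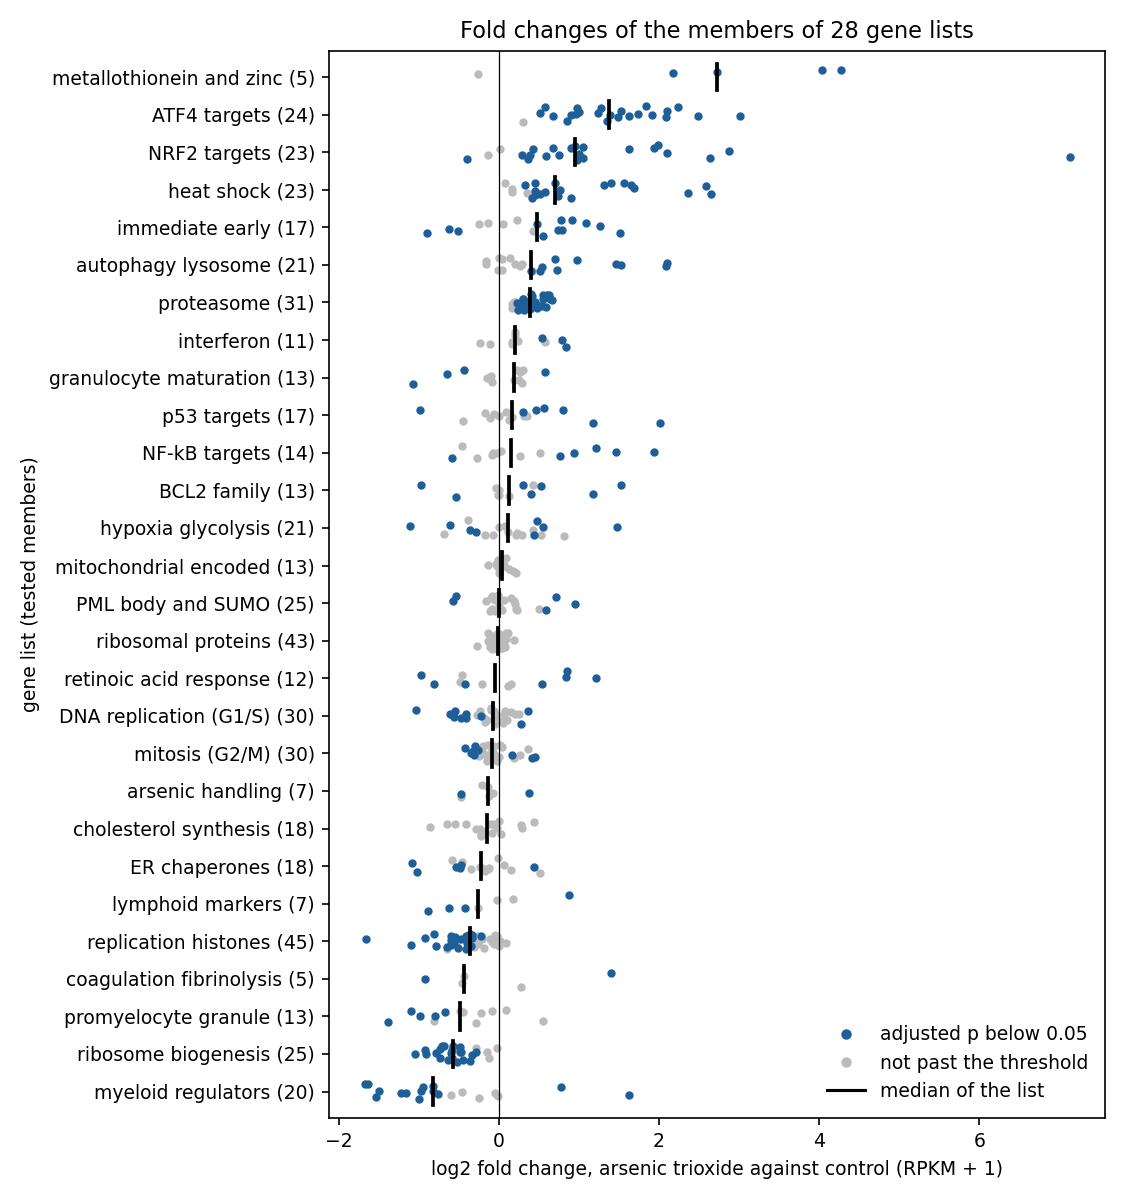
Log2 fold change (arsenic trioxide minus control) of each tested member of the 28 gene lists with a set test, with called members in colour and the list's median as a bar. The integrated stress response list, shown as ATF4 targets (median 1.37), heat shock (0.70) and NRF2 (0.95) lists lie mostly to the right of 0, and the ribosome biogenesis (-0.57) and myeloid regulator (-0.83) lists lie mostly to the left.

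In the metallothionein and zinc list 4 of 5 members rose, or 4 with 1 lower when adjusted over the list alone (median log2 fold change 2.73, camera adjusted p = 0.000125, and adjusted p = 0.145 with an estimated correlation). Besides MT2A, MT1X and MT1F it included the zinc exporter SLC30A1 (2.18). In the NRF2 antioxidant list 20 of 23 members rose and 1 fell, and 20 rose and 1 fell adjusted over the list alone. Its median was 0.95 (camera adjusted p = 7.47e-11, and adjusted p = 0.214 with an estimated correlation). After HMOX1 and SLC7A11 its smallest p-values belonged to GCLM, a subunit of the enzyme that limits glutathione synthesis (1.94, from 8.01 ± 0.848 to 33.6 ± 5.28 RPKM), and to FTH1, the ferritin heavy chain (1.98), which has many processed pseudogenes that can share its reads. The member that fell, UGDH (-0.40, limma-trend adjusted p = 0.0195), named after its values were seen, lost the call without control replicate 3 (adjusted p = 0.0702) or arsenic trioxide replicate 1 (0.0571). In the heat shock list 19 of 23 members rose, or 21 adjusted over the list alone (median 0.70, camera adjusted p = 9.35e-14, and adjusted p = 0.148 with an estimated correlation). HSPA1A, an inducible HSP70 chaperone, rose from 2.0 ± 0.367 to 16.9 ± 0.669 RPKM (2.58) and its near-identical copy HSPA1B from 28.8 ± 7.02 to 182 ± 2.76 RPKM (2.65), so the division of reads between the copies is uncertain. The cochaperones DNAJB1 (1.66) and BAG3 (1.69) rose with them.

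The integrated stress response list, made up mainly of targets of the transcription factor ATF4, rose in 23 of 24 members, or 24 adjusted over the list alone (median 1.37, camera adjusted p = 3.65e-17, and adjusted p = 0.145 with an estimated correlation). Its members include the serine synthesis enzyme PSAT1 (1.74), the amino acid transporter subunit SLC3A2 (0.98), the phosphatase subunit PPP1R15A (2.1) and CEBPB (1.62). DDIT3, which encodes CHOP, rose from 4.68 ± 1.57 to 23.1 ± 5.88 RPKM (2.09, limma-trend adjusted p = 0.00235) and ATF3 from 0.818 ± 0.146 to 4.34 ± 1.41 RPKM (1.52, adjusted p = 0.00413). The remaining member was NARS (0.30, adjusted p = 0.0581), named after its values were seen, which was called without arsenic trioxide replicate 3 (0.00885), with limma-voom (0.0208), with the filter at 1 CPM (0.0416), without structural RNA genes (0.041) and without overlapping genes (0.0419). The endoplasmic reticulum chaperone list moved the other way, with 1 of 18 members higher and 5 lower, or 1 and 6 adjusted over the list alone (median -0.22, camera adjusted p = 0.0348, and adjusted p = 0.505 with an estimated correlation). Besides chaperones the list holds genes with other roles, such as XBP1, SEL1L, SYVN1 and EDEM1. MANF (-1.02), HYOU1 (-0.48) and SDF2L1 (-1.08) fell, and EDEM1, which sends misfolded proteins to degradation, rose (0.43). HSPA5, the main chaperone of this compartment and named after its values were seen, was at -0.46 (limma-trend adjusted p = 0.1), and was called without control replicate 1 (0.0355) and with limma-voom (0.0208). The call of this list was lost without control replicate 3 (adjusted p = 0.126), without arsenic trioxide replicate 3 (0.0848) and in fry (0.0887).

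In the proteasome list 24 of 31 subunits were higher, or 30 adjusted over the list alone (median 0.38, camera adjusted p = 9.35e-14, and adjusted p = 0.145 with an estimated correlation), among them PSMD11 (0.63), PSMD13 (0.61), PSMC6 (0.66) and PSMD1 (0.54). In the autophagy and lysosome list 10 of 21 members rose, or 13 adjusted over the list alone (median 0.40, camera adjusted p = 2.85e-05, and adjusted p = 0.145 with an estimated correlation). These include the autophagosome proteins GABARAPL1 (2.08) and MAP1LC3B (1.53), the cargo receptor SQSTM1 (2.1) and the transcription factor TFE3 (0.98).

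Of the regulators of the myeloid lineage, 12 of 20 members fell and 2 rose, or 13 and 2 adjusted over the list alone (median -0.83, camera adjusted p = 1.3e-05, and adjusted p = 0.145 with an estimated correlation). GFI1 (-1.64, limma-trend adjusted p = 0.000257), MYC (-1.67, adjusted p = 0.000368), ZEB2 (-1.49) and MYB (-1.53) had the smallest p-values, and CEBPB was among the members that rose. In the promyelocyte granule list 5 of 13 members fell and 0 rose, or 8 and 1 adjusted over the list alone (median -0.48, camera adjusted p = 0.00921, and adjusted p = 0.499 with an estimated correlation), among them AZU1 (-0.98), PLAC8 (-0.80), MS4A3 (-0.68) and RNASE3 (-1.38). The calls of MS4A3 and RNASE3 were lost without control replicate 2 (adjusted p = 0.0621 and 0.0626) or 3 (0.0667 and 0.0713), without arsenic trioxide replicate 2 (0.0546 and 0.0539) and with the replicate number as a block (0.0603 and 0.0664). PRTN3, which was not called (adjusted p = 0.228) and is named after its values were seen, was at 81.8 RPKM in control replicate 1 and 164 and 186 RPKM in the other controls, and at 122, 91.0 and 40.9 RPKM in arsenic trioxide replicates 1, 2 and 3. The granulocyte maturation list did not pass, with 1 of 13 members higher and 3 lower, including the Fc receptor FCGR1A (-1.07) and the oxidase subunit CYBB (-0.44). The call of the higher member, S100A9 (0.58, limma-trend adjusted p = 0.0464), was lost without any 1 of the 6 libraries (0.0566 to 0.118), with limma-voom (0.0806), with no filter (0.0667) and with a pseudocount of 0.1 (0.0529). MNDA, a lower member (-0.64), lost its call without control replicate 2 (adjusted p = 0.0741) or 3 (0.0754), without arsenic trioxide replicate 1 (0.063) or 3 (0.0603) and with the block (0.0671). The list's median was 0.20 and its test pointed up (camera adjusted p = 0.961), while its mean was -0.03 and its median was -0.07 without arsenic trioxide replicate 3. The retinoic acid response list had 4 of 12 members higher and 3 lower (median -0.05 with a test that pointed down, camera adjusted p = 0.915), while its mean was 0.03. TNFSF10 (-0.97) and RARRES1 (-0.81) fell and IRF1 (0.84) rose in this list.

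Ribosome biogenesis genes fell in 21 of 25 members, or 22 adjusted over the list alone (median -0.57, camera adjusted p = 4.84e-12, and adjusted p = 0.186 with an estimated correlation). POLR1B, a subunit of RNA polymerase I (-0.92), and the nucleolar proteins GNL3 (-0.73), NOP16 (-1.05) and NOLC1 (-0.57) were among them. Of 43 ribosomal protein genes, 0 were called by limma-trend, with 2 at an unadjusted p under 0.05 and 2 called by limma-voom on the recovered reads (median -0.01, camera adjusted p = 0.819). Replication-dependent histone genes fell in 23 of 45 members, or 33 adjusted over the list alone (median -0.36, camera adjusted p = 2.29e-09, and adjusted p = 0.395 with an estimated correlation). HIST1H4I (-0.92), HIST1H4B (-0.60), HIST1H4L (-1.10) and HIST1H2AB (-0.79) are examples, and histone copies of one family can share reads. In the G1/S and replication list 2 of 30 members rose and 8 fell (median -0.08, camera adjusted p = 0.0372, and adjusted p = 0.505 with an estimated correlation), led by MCM7 (-1.04), UHRF1 (-0.60), MCM3 (-0.54) and MCM4 (-0.41). That call was lost without control replicate 1 (adjusted p = 0.0654) or 3 (0.0615), without arsenic trioxide replicate 2 (0.126) and in fry (0.0504), and the median was -0.12 without arsenic trioxide replicate 3. The G2/M and mitosis list had 3 of 30 members higher, such as TTK (0.42), and 6 lower, such as ESPL1 (-0.43) and CCNA2 (-0.31), and did not pass (median -0.08, camera adjusted p = 0.193).

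The p53 target list passed upward with 6 of 17 members higher and 1 lower, or 7 and 2 adjusted over the list alone (median 0.17, camera adjusted p = 0.0372, and adjusted p = 0.214 with an estimated correlation). GADD45A (2.01), BBC3 (1.17) and CCNG1 (0.47) rose and AEN (-0.98) fell, and the list's call was lost without control replicate 1 (adjusted p = 0.0503). Immediate early genes rose in 9 of 17 members and fell in 3, also adjusted over the list alone (median 0.48, camera adjusted p = 0.0237, and adjusted p = 0.236 with an estimated correlation). JUN (1.51), DUSP1 (1.09), JUND (0.74) and IER5 (0.79) rose, and without arsenic trioxide replicate 2 the list's adjusted p was 0.0531. The interferon list had 3 of 11 members higher and 0 lower, also adjusted over the list alone (median 0.21, camera adjusted p = 0.0372, and adjusted p = 0.499 with an estimated correlation), including IRF1 and STAT2 (0.79). This call was lost without control replicate 1 (adjusted p = 0.0741), without arsenic trioxide replicate 3 (0.0952, median 0.09) and in fry (0.0509), and the median was 0.31 without arsenic trioxide replicate 1.

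The BCL2 family list, regulators of apoptosis, did not pass (median 0.13, camera adjusted p = 0.124) with 5 of 13 members higher and 2 lower, or 6 and 2 adjusted over the list alone. It passed without overlapping genes (median 0.52, adjusted p = 0.00525) and in fry (0.000661). PMAIP1, which encodes the proapoptotic NOXA, rose (1.53) with MCL1 (0.40), and BCL2 fell (-0.97). The NF-kB list had 5 of 14 members higher and 1 lower (median 0.15, camera adjusted p = 0.193), with rises of CXCL8 (1.94), CXCL2 (0.93) and ICAM1 (1.47). The lower member, NFKBIE (-0.59), lost its call without control replicate 2 (adjusted p = 0.0766) or 3 (0.0764), without arsenic trioxide replicate 1 (0.0573) or 3 (0.0644) and with the block (0.0514). In the PML body and SUMO list 3 of 25 members rose, among them UBB (0.72) and HIPK2 (0.58), and 2 fell, DAXX (-0.53) and SENP3 (-0.58). Its median was -0.0022, while its mean was 0.08 and its test pointed up (camera adjusted p = 0.321), and it passed in fry (0.0131). Of 7 arsenic handling genes GSTP1 rose (0.38) and 1 fell, the channel gene AQP3 (-0.47), whose call was lost without any 1 of the 6 libraries (adjusted p = 0.0522 to 0.131). This list had 1 higher and 3 lower adjusted over the list alone and did not pass (median -0.14, camera adjusted p = 0.323), except in fry (0.0197). Of 5 coagulation and fibrinolysis genes ANXA2 rose (1.4) and F3, the tissue factor gene, fell (-0.92), or 2 and 3 genes adjusted over the list alone, with a list median of -0.43 (camera adjusted p = 0.89).

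In the hypoxia and glycolysis list 4 of 21 members rose, among them VEGFA (1.47), and 4 fell, among them HK2 (-1.11), or 6 and 4 adjusted over the list alone, and the list did not pass (median 0.11, camera adjusted p = 0.601), except without overlapping genes (median 0.47, adjusted p = 0.020). The cholesterol synthesis list had 0 of 18 members called by limma-trend, with 4 at an unadjusted p under 0.05 and 4 called by limma-voom (median -0.15, camera adjusted p = 0.379). Without arsenic trioxide replicate 3 it passed downward (median -0.40, adjusted p = 0.000251) at the preset correlation of 0.01. The correlation estimated over all 6 libraries was 0.878, at which the list did not pass (adjusted p = 0.964), nor did it in fry (0.729). The 13 genes encoded by mitochondrial DNA had 0 calls by limma-trend, with 0 at an unadjusted p under 0.05 and 1 called by limma-voom (median 0.04, camera adjusted p = 0.654). Among lists of other cell types, the lymphoid list had 1 of 7 members higher and 3 lower, including CD4 (-0.42), and did not pass (median -0.26, camera adjusted p = 0.391). CD79B and TRAC, also lower, lost their calls without control replicate 3 (limma-trend adjusted p = 0.0575 and 0.102) or arsenic trioxide replicate 1 (0.0531 and 0.0976). The call of TRAC was also lost without control replicate 1 (0.1) or arsenic trioxide replicate 2 (0.104). The erythroid and megakaryocyte list had 3 tested members with 0 higher and 1 lower, the monocyte list 2 tested members with 0 calls and the epithelial and stromal list 3 tested members with 0 calls, too few for the set test. The lower member, TFRC, lost its call without control replicate 3 (limma-trend adjusted p = 0.0698) and without arsenic trioxide replicate 1 (0.0792), 2 (0.0875) or 3 (0.0688). In the monocyte list and in the epithelial and stromal list 0 members had an unadjusted p under 0.05 and 0 were called by limma-voom.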

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

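Leaving out genes that overlap another gene was chosen after the data were seen, and the other alternatives were fixed before. Of 28 list medians and 164 named genes over all alternatives, 443 and 2439 values kept direction and side of the threshold, 33 and 69 lost the call, 6 and 39 gained it, and 19 and 5 changed sign. Across the scaling, filter, pseudocount and tool settings, calls went from 4185 with a pseudocount of 0.1 to 5243 with limma-voom, of which 3990 were shared with the 4273 reported. Higher genes numbered 1331 to 1525 and lower genes 1427 to 1908 with 1 library left out, where fewer samples are compared. Without overlapping genes, where 5290 genes were tested, they numbered 794 and 1078 (42.4% higher against 47.3%), with 120 and 112 changed at least 2-fold. Genes higher or lower at least 2-fold numbered 626 and 509 with limma-voom, 564 and 464 with a pseudocount of 0.1, and 87 and 58 with a pseudocount of 5. A larger pseudocount shrinks the fold of low values by construction. Lists past the set test numbered 0 with an estimated correlation and 15 with fry.

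Same-numbered libraries did not pair. Their deviations from the group means correlated at -0.085, 0.148 and -0.083, and control replicate 1 correlated best with arsenic trioxide replicate 3 (0.221). With the replicate number as a block, 3076 genes were called (1460 higher, 1616 lower), of which 2943 were shared. The block ended 8 calls among the named genes and lists, including RARA (adjusted p = 0.0682), AQP3 (0.0729) and the G1/S list (0.0559).

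Sign changes concerned values without a call, and the cause was not tested. With 1 library left out, log2 fold changes ranged from -0.109 to 0.0478 for SPI1, -0.416 to 0.0242 for GATA1, -0.0339 to 0.213 for GP1BA and -0.0656 to 0.178 for EPCAM. List medians then ranged from -0.0665 to 0.196 for granulocyte maturation, -0.00777 to 0.0258 for PML bodies and SUMO, -0.0429 to 0.0224 for ribosomal proteins and -0.0992 to 0.127 for mitochondrial genes. The retinoic acid median was 0.0324 with no filter, 0.0732 with the filter at 1 CPM and 0.13 without overlapping genes. The coagulation median was 0.19 with no filter and 0.18 with that filter. The PML body median was 0.00445 with median-ratio factors, 0.000411 with upper quartile factors and 0.00809 with no filter or the filter at 1 CPM.

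MPO passed with limma-voom (adjusted p = 0.00679), without structural RNA genes (0.0483) and without overlapping genes (0.047), in a range up to 0.195. The p53 list was lost with the filter at 1 CPM (0.0534), and the interferon list with that filter (0.126), with no filter (0.0763) and without overlapping genes (0.246). The G1/S list was also lost without overlapping genes (0.187), where the BCL2 family (0.00525) and hypoxia (0.020) lists passed. Total reads as the only scaling is what RPKM already holds. Factors inside count tools and a count-model test were not run on the recovered reads. LUCAT1, at low RPKM in the controls, had a log2 fold change of 3.18 as reported, 5.78 with limma-voom and 1.51 with a pseudocount of 5. At this depth and with 3 libraries per group, limma-trend recovered 27.3% of simulated 1.5-fold changes. That simulation had 141 calls where the real data had 4273. The adjusted threshold is stricter where few genes change, so this share does not carry over to the real data.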

Other observations

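The genes and groups of this paragraph and the next were chosen after their values were seen. They stand as single values, and no group test is given for them, as they were picked for their change. Chosen after the result was seen were also the tests on ribosome biogenesis and on endoplasmic reticulum chaperones, while the test on genes inside other genes and the splits of the libraries were written before their results. C5AR1, the receptor of complement fragment C5a, rose from 2.72 ± 1.08 to 9.69 ± 1.22 RPKM (SD, n = 3 each; log2 fold change 1.55, limma-trend adjusted p = 0.00327), and C3AR1, the receptor of C3a, fell from 10.3 ± 2.53 to 2.93 ± 0.411 RPKM (-1.51). CXCR4, a homing receptor, fell from 14.7 ± 3.60 to 5.86 ± 1.71 RPKM (-1.20, limma-trend adjusted p = 0.00976), the nucleotide receptor P2RY2 from 80.0 ± 9.68 to 21 ± 2.25 RPKM (-1.88), and PTGER4, a prostaglandin receptor, had -1.19. TERT, the catalytic subunit of telomerase, fell from 3.93 ± 0.564 to 0.949 ± 0.0932 RPKM (-1.33, limma-trend adjusted p = 0.00143), and IKZF1, the Ikaros transcription factor, from 41.6 ± 2.44 to 19.3 ± 0.0599 RPKM (-1.07). Rises included those of the haem transporter SLC48A1 (2.24, from 7.53 ± 0.104 to 39.3 ± 4.83 RPKM) and FECH, which inserts iron in the last step of haem synthesis (1.01). The stress factor ATF5 (2.16) and INHBE (2.59, from 0.328 ± 0.128 to 7.20 ± 2.22 RPKM) also rose. AKR1C4, an aldo-keto reductase with near-identical relatives, was at 0.355 ± 0.146 and 3.75 ± 0.458 RPKM (1.81).

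In the T cell receptor gamma locus, where the fall of TRGJ1 was noticed, the 7 tested joining and constant genes were all called lower (median log2 fold change -1.72), among them TRGC1 (-1.27, from 11.8 ± 0.391 to 4.44 ± 1.37 RPKM), TRGJ2 (-1.88) and TRGJP1 (-1.72). Genes of one locus are not independent, and these 7 had a median of 32 reads per library. Over all 17 tested gamma genes, variable genes included, 8 were lower and 3 higher (median -0.52), with TRGV10 at -1.46. Of 235 small nucleolar RNA genes 38 were lower, 16.2% against 13.4% of the other tested genes, and 18 were higher (median -0.17). The 2 shares lie close together, so a fall of the class as a whole is not shown. SNORD20 (-0.91) lies within NCL, which had -0.34.

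Non-coding genes that lie inside protein-coding genes moved with their hosts. Over 3410 pairs whose starts lie more than 10 kb apart, Spearman's rho of the log2 fold changes was 0.632 (95% bootstrap interval 0.608 to 0.655, across genes, which are not independent replicates), against 0.345 (0.289 to 0.397) for 1205 pairs of neighbours within 50 kb that do not overlap. The prediction written before, that a shared promoter as the whole cause would leave rho at 0.1 or less, was not met. That limit was too low, since neighbours that do not overlap already had 0.345. Starts were taken as the outer gene ends, so promoters within a host were not considered. The 608 inside pairs with starts within 10 kb had 0.630 (0.569 to 0.680), so rho was not higher for closer starts. A shared promoter is therefore not excluded by the distance. The excess of 0.287 (0.231 to 0.349) is consistent with reads of unspliced host RNA counted in the inner gene, as rRNA-depleted total RNA without strand would give, and rho was 0.628 on the same and 0.635 on opposite strands. Changes of intronic and antisense genes may therefore be those of their hosts, while shared regulation of a region stays open.

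Ribosome biogenesis genes fell in 21 of 25 members, with a median of -0.57 (95% bootstrap interval -0.69 to -0.44, 25 genes). The list's call was lost with an estimated correlation (0.287, camera adjusted p = 0.186), and intervals resampled over genes that vary together can be too narrow. A trend of fold change with GC content, exon length or expression level would leave a median near 0 once removed, and it was -0.51 (-0.57 to -0.36). That value argues against such a trend as the cause. The 10 most abundant genes held 3.76 ± 0.0557% of reads after treatment and 3.01 ± 0.0153% in controls (SD, n = 3 each). An exact two-sided permutation test gave p = 0.1, the smallest possible. Stress transcripts taking a larger part of the reads would lower the other genes alike. The median log2 fold change of all tested genes was -0.0033, and 0.0023 under median-ratio factors, which argues against this as the cause of a fall of such size. These factors could hardly move any list, so the list's median under them, -0.56 (-0.68 to -0.44), was all but fixed in advance and adds no support. A response to arsenic trioxide, the only factor between the groups that the labels name, may remain as a hypothesis found and tested on the same data.

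The genes of the endoplasmic reticulum chaperone list, not all of them chaperones, did not rise with the ATF4 targets. The median of the integrated stress response list lay 1.59 (95% bootstrap interval 1.19 to 2.03) above theirs on the log2 scale. Duplicate removal could flatten abundant genes. The 17 heat shock genes at least as densely covered as the median endoplasmic reticulum gene had a median of 0.58 (0.45 to 1.41). The heat shock list had already been seen to rise, so this value shows only that rises at such coverage were not erased. It cannot decide whether folds of the endoplasmic reticulum genes were flattened. A trend with GC content, exon length or expression level is argued against by the difference after its removal, 1.62 (1.22 to 2.07). No biological explanation was tested.

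The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. In 1 of the 10 splits, the real one, 2021 genes were higher and 2252 lower by limma-trend, with 343 and 260 at least 2-fold, and the highest count in any other split was 0, with 273 to 618 genes at an unadjusted p under 0.05. The real split gave 15 lists past the camera test, and the other splits gave 5 to 13, each with 0 called genes. Each of the other splits mixes treated and control libraries on both sides, so the treatment difference widens the spread within each side. A lack of called genes there can follow from that mixing, and the lists called there can carry part of the treatment difference. The splits therefore cannot tell whether chance gave the counts.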
